A study of Mus musculus with 16 samples.

How the data were processed

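Messenger RNA was measured by RNA sequencing in macrophages grown from mouse bone marrow. Per the labels, the mice were C57BL/6 animals of 8 weeks, either wild type or carrying Sirt3 K223R, a change of lysine to arginine in the mitochondrial deacetylase Sirt3. Bone marrow cells were grown for 7 days with M-CSF at 20 ng/ml, the growth factor that turns them into macrophages, and were left untreated or given IL-4 at 20 ng/ml for 24 hours, a cytokine that drives alternative (M2) activation. The 16 libraries form 4 groups of 4. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates came from separate mice, so the p-values measure the spread between these samples, which may in part be technical.

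Per the labels' protocols, RNA was extracted with Trizol, enriched by poly(A) selection or alternatively by removal of ribosomal RNA, made into stranded dUTP libraries and sequenced from both ends. Which enrichment was used for which library is not stated. The deposited value per gene is taken as FPKM, fragments scaled to transcript length and to library size: the file headers name no unit, and FPKM was inferred because the values are not whole numbers and sum to between 288143 and 306581 per library over 10920 protein-coding genes. TPM of a larger gene set cannot be excluded. The low values are not whole multiples of a value of 1 read, so the sequencing depth is unknown and no counting interval can be given; the spread between the 4 libraries of a group is the measure of precision. Aligner, counting tool, strand setting and genome build are not given in the sources used here. The coordinates in the files equal those of GENCODE M21 on GRCm38 for all 9510 gene identifiers found there with the same version, and coordinates are given on that build. The files of the Sirt3 K223R libraries carry a gene type column that the wild-type files lack, so a difference in the authors' processing between genotypes would coincide with genotype. Each file held 1 blank line, which was left out. Of the pairs of libraries, 0 shared the greater part of their values, and none was merged.

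Values were set on a log2(FPKM + 1) scale, with a pseudocount of 1, which understates changes of low genes. Genes entered if the value was at least 1 in at least 4 libraries, which left 9891 genes. A linear model with 4 group means was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and 5 contrasts were tested: IL-4 against untreated cells in each genotype, Sirt3 K223R against wild type in untreated and in IL-4 cells, and the interaction, which is the difference of the 2 IL-4 responses. P-values were adjusted by the Benjamini-Hochberg method over genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values of genes are from limma. On simulated data with changed genes spread over the real values, 70.1% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered for the wild-type IL-4 contrast, and 58.2%, 92.5% and 97% for the interaction, with 8 and 3 false calls.

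Before the data were examined, 35 gene lists were fixed, among them markers of other cell types, and 27 had enough tested members. Lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry, which asks whether members move on balance in a single direction. Members called were counted over all genes and, separately, adjusted over the list alone. List scores per library (the mean over members) and single values were compared with a 2-sided exact permutation test of 4 against 4 libraries, whose smallest possible p is 0.0286. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for these steps.

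Genes were named by a rule fixed before the data were examined. It takes Sirt3, for each comparison up to 10 called genes with the largest change in each direction whose higher group mean was at least 1 and whose 4 and 4 libraries did not overlap (without the overlap rule for the interaction), up to 4 members of each list with the smallest adjusted p or, where none passes, up to 2 with the highest mean level, and Arg1, Chil3, Retnla and Mrc1 throughout. Gene models without a proper symbol were counted and not named. A few genes are counted in totals, and their own results are not reported here. Genes named outside the rule are said to be so where they appear. How reads of near-identical genes were divided is not given, so values of Chil3 and Chil4, of Rnase2a and Ear2, and of Il11ra2, Sirpb1a, Pilrb2, Clec4n, Ctla2b and histone genes, which have close relatives, and of Itgam, which overlaps a second identifier, are uncertain.

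Same-numbered libraries of untreated and IL-4 cells were checked for pairing from the correlation across genes of their deviations from the group means. In wild type all 4 pairs lay above 0.1, at 0.286, 0.122, 0.1001 and 0.116, each library correlated best with its own number, and the numbers were therefore read as pairing the wild-type libraries; this comes from the data, and the labels do not state it. A fit with the replicate number as a block is given beside a wild-type result where it changes a call. Other alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, quantile normalization, a fit on the compared groups alone, array weights, a 2-fold minimum and leaving out each library in turn. A test on read counts could not apply to values that are not whole counts and was not run.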

Results

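The series asks how macrophages from mice with Sirt3 K223R differ in gene expression from wild-type macrophages, at rest and after IL-4. It holds 4 libraries each of untreated wild-type cells, wild-type cells with IL-4, untreated Sirt3 K223R cells and Sirt3 K223R cells with IL-4. The depth of sequencing is unknown, because the values, taken here as FPKM, are not whole counts. Per library, the median FPKM over the genes in the files lay between 5.37 and 6.18. The share of summed FPKM in the 10 highest genes was 19.3% ± 0.533 in untreated wild-type cells and 16.3% ± 0.515 with IL-4 (SD, n = 4). It was 19.3% ± 0.849 and 19.2% ± 1.68 in the corresponding Sirt3 K223R cells. The first principal component, with 56.3% of the variance, parted IL-4 from untreated libraries. Sirt3 K223R libraries with IL-4 lay between 27.1 and 28.6 on it and wild-type libraries with IL-4 between 14.2 and 16.9. Sirt3 K223R with IL-4 replicate 2 stood apart on the second component at 17.7, where the other libraries of its group lay between 3.78 and 6.04. Its median correlation with its own group was the lowest of the 16 libraries at 0.98.

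**Figure D1:**
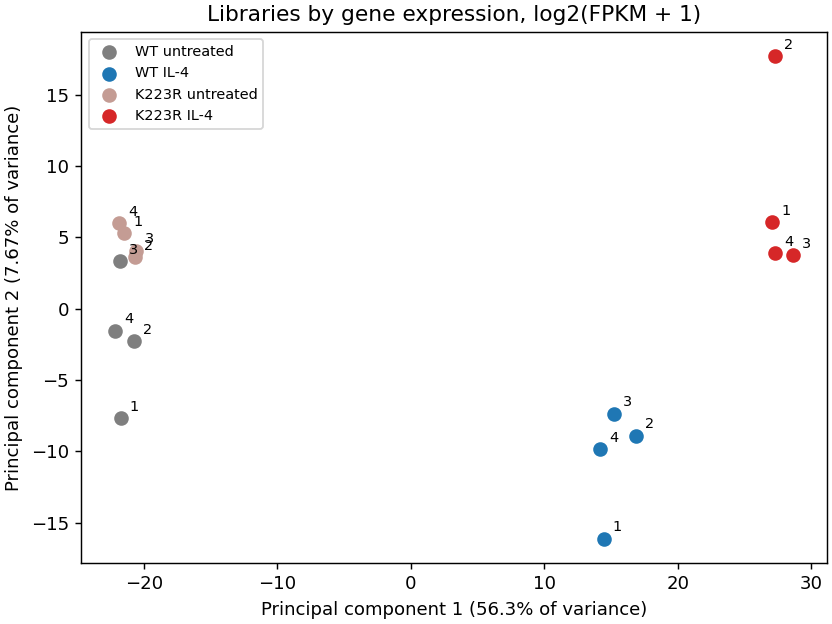
Each point is a library, placed by its scores on the first (56.3% of variance) and second (7.67%) principal components of log2(FPKM + 1); colours give the 4 groups and digits the replicate numbers. Untreated and IL-4 libraries part on the first component, and replicate 2 of Sirt3 K223R with IL-4 lies at 17.7 on the second.

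Sirt3 itself (ENSMUSG00000025486.17, GRCm38 chromosome 7, 140863666 to 140882309) was a low transcript in every group. Its mean FPKM was 1.48 ± 0.168 in untreated and 1.36 ± 0.233 in IL-4 wild-type cells, and 1.56 ± 0.135 in untreated and 1.32 ± 0.101 in IL-4 Sirt3 K223R cells (SD, n = 4). Between genotypes the difference was within the spread of the libraries, with exact permutation p of 0.543 in untreated and 0.800 in IL-4 cells. With IL-4 the level did not differ in wild type (exact permutation p = 0.457). In Sirt3 K223R cells it was lower by the exact test (p = 0.0286, the smallest it can give). Limma did not call it (adjusted p = 0.157), and median-ratio scaling moved the exact p to 0.171. K223R changes the protein sequence, so the mRNA level does not check the genotype labels.

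In wild-type macrophages IL-4 raised Retnla, Chil3 and Arg1, established genes of alternative activation, by large factors and lowered Cd14 and the chemokines Ccl3 and Ccl4. Retnla, a secreted resistin-like protein, rose from 1.4 ± 0.578 to 1200 ± 326 FPKM (SD, n = 4). Chil3, a chitinase-like protein, rose from 13.8 ± 5.18 to 1907 ± 384, and Arg1, the enzyme that splits arginine, from 2.05 ± 1.32 to 320 ± 41.6. Cd14, the co-receptor for lipopolysaccharide, fell from 211 ± 24.9 to 54.5 ± 3.86. Among 9891 genes, limma called 2575, of which 1057 rose and 1518 fell, 168 and 80 of them by at least 2-fold.

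The largest rises on the log2(FPKM + 1) scale were those of Retnla (8.94, SE 0.45, adjusted p = 1.47e-09; GRCm38 chromosome 16, 48842552 to 48844461) and Chil3 (7.06, SE 0.24, adjusted p = 2.07e-11; chromosome 3, 106147554 to 106167564). Next came Arg1 (6.81, SE 0.26, adjusted p = 7.08e-11; chromosome 10, 24915221 to 24927484) and Rnase2a, an eosinophil-type ribonuclease (6.69, SE 0.34). Mgl2, a lectin of alternatively activated macrophages, rose by 5.15, the checkpoint ligand Pdcd1lg2 by 4.14, and the amino acid oxidase Il4i1 by 3.56. Also among the 10 largest rises were Tmem26 (3.49), the ribonuclease Ear2 (3.19) and Apol7c (3.12). Mrc1, the mannose receptor, rose by 2.17 (SE 0.12). The largest falls were those of Arhgap19 (-3.18), the lectin receptor Clec4n (-2.06) and Cd14 (-1.93). Arhgap19 was uneven, at 0.703, 4.41, 0.752 and 22.3 FPKM in the 4 IL-4 libraries against 29.5 to 43.8 in untreated cells. The chemokines Ccl3 (-1.71) and Ccl4 (-1.69), the pattern receptors Tlr2 (-1.68) and Clec4d (-1.56), Marcksl1 (-1.60), Sirpb1a (-1.52) and Pilrb2 (-1.49) completed the 10 largest falls.

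Of 32 tested genes of the list for IL-4 alternative activation, 31 rose and 0 fell. When adjusted over the list alone 31 rose and 1, the IL-4 receptor chain Il4ra (-0.20), fell (camera adjusted p = 1.86e-39, and adjusted p = 0.000226 with an estimated correlation). In the list for classical inflammatory activation, 6 of 12 genes fell, among them Tnf (-1.37) and Cxcl2 (-1.32), and 1, Cd40 (0.41), rose, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0325, and adjusted p = 0.432 with an estimated correlation). For nuclear-encoded oxidative phosphorylation, 30 of 76 genes rose and 0 fell, with Ndufs8 (0.54) and Atp5o (0.50) of the respiratory chain and ATP synthase among them. Adjusted over the list alone 33 rose (camera adjusted p = 4.61e-13, and adjusted p = 0.126 with an estimated correlation). For the tricarboxylic acid cycle, 10 of 24 genes rose, such as Idh3a (0.44) and Sdhd (0.24), and 11 adjusted over the list alone (camera adjusted p = 6.94e-06, and adjusted p = 0.0136 with an estimated correlation). For fatty acid oxidation, 9 of 23 genes rose, such as Etfa (0.38) and Hadha (0.37), and 2, Cpt1a (-0.39) and Lipa (-0.20), fell, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.126 with an estimated correlation). The call for Lipa, the lysosomal lipase, was lost without untreated wild-type replicates 1, 3 and 4 or IL-4 wild-type replicate 2 (adjusted p up to 0.0744). Members that are the few exceptions of a list were, here and in the other comparisons, named after their values were seen.

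Among genes of cholesterol biosynthesis, 12 of 22 rose, such as Hmgcs1 (0.37) and Mvd (0.36), and 1, Sc5d (-0.38), fell, with 14 and 1 adjusted over the list alone (camera adjusted p = 2.39e-05, and adjusted p = 0.169 with an estimated correlation). For MHC class II presentation, 7 of 8 genes rose, and 8 adjusted over the list alone, with H2-DMa at 1.75, the invariant chain Cd74 at 1.69 and H2-Ab1 at 1.56 (camera adjusted p = 1.38e-05, and adjusted p = 0.232 with an estimated correlation). In the list of NRF2 targets and antioxidant enzymes, 17 of 24 genes fell, such as Gsr (-0.85), Sod1 (-0.81) and Cat (-0.69), and 3, Txn2 (0.25), Slc7a11 (0.23) and Gpx4 (0.16), rose. The call for Slc7a11 was lost without untreated wild-type replicate 2 or IL-4 wild-type replicate 1 (adjusted p up to 0.0742), and that for Txn2 without IL-4 wild-type replicate 4 (adjusted p = 0.0502). Gpx4 lost its call without untreated wild-type replicates 1, 3 and 4 or IL-4 wild-type replicates 1, 2 and 3 (adjusted p up to 0.0864). It was also lost with quantile normalization (adjusted p = 0.466), and that of Slc7a11 in a fit on the wild-type groups alone (adjusted p = 0.0796). When adjusted over the list alone 17 antioxidant genes fell and 5 rose, Tkt and Nqo1 being added (camera adjusted p = 0.00154, and adjusted p = 0.232 with an estimated correlation). With the replicate number as a block Nqo1 was called over all genes too (adjusted p = 0.0156), and with the number as a random effect both were (adjusted p = 0.0467 for Nqo1 and 0.0379 for Tkt). Of 7 osteoclast genes, 4 rose, Ocstamp (3.01), Itgb3 (1.68), Dcstamp (1.05) and Acp5 (0.83), and 1, Nfatc1 (-0.19), fell. Adjusted over the list alone Ctsk joined the former and Mmp9 the latter (5 and 2; camera adjusted p = 0.00174, and adjusted p = 0.0938 with an estimated correlation). With the block both were called over all genes (adjusted p = 0.0228 and 0.00299). Nfatc1, a transcription factor of osteoclasts, lost its call without untreated wild-type replicates 1, 3 and 4 or IL-4 wild-type replicates 3 and 4 (adjusted p up to 0.0984) and with median-ratio scaling (adjusted p = 0.0552), quantile normalization (0.0504) or a fit on the wild-type groups alone (0.051).

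Markers of other cells moved as follows in wild type. Of 7 tested neutrophil and granulocyte precursor genes, 4 fell, the granule genes Camp (-1.22), Ngp (-0.99), Lcn2 (-0.79) and Ltf (-0.79). When adjusted over the list alone 5 fell, with S100a8 added, which was called over all genes with the replicate block (adjusted p = 0.00443). Camera gave the neutrophil list an adjusted p of 0.0893, which was 0.0259 with the replicate number as a block, and adjusted p = 0.61 with an estimated correlation and 0.0129 with fry. The call for Ltf was lost without untreated wild-type replicates 3 and 4 or IL-4 wild-type replicates 1 and 2 (adjusted p up to 0.0739), and a fit on the wild-type groups alone ended those of Ltf and Lcn2 (adjusted p = 0.0607 and 0.0526). Most markers of dendritic, B, T and NK, mast, erythroid and stromal cells are not analysed here. Batf3, counted with dendritic cells and also among the IL-4 genes, rose by 2.26. Chil3, described above, is also 1 of the 2 tested genes of the monocyte list. The other, Ccr2, was called in 0 comparisons (0.31 with IL-4 in wild type, -0.13 between genotypes with IL-4). With the replicate block it was higher with IL-4 in wild type (adjusted p = 0.0201) and in Sirt3 K223R (0.0339). Of the erythroid genes Car2, a carbonic anhydrase also made in osteoclasts, was the only tested member and rose by 0.92. The stromal genes Acta2 and Sparc fell (-0.87 and -0.30). In Sirt3 K223R cells the responses of Batf3, Car2, Acta2 and Sparc were 2.57, 0.94, -1.29 and -0.83, all past the threshold. Of 15 macrophage identity genes 2 rose in wild type, among them Itgam, of whose 2 overlapping identifiers 1 was called, and 5 fell, such as the Fc receptor Fcgr1 (-0.95). The same 2 genes rose and 6 fell in Sirt3 K223R cells (camera adjusted p = 0.428 in wild-type and 0.542 in Sirt3 K223R cells). Camera called the macrophage list in wild type with quantile normalization (adjusted p = 0.0314), and fry called it in both genotypes (adjusted p = 0.00232 and 0.000385). With an estimated correlation it was not called in either (adjusted p = 0.921 in wild type). Cd79b of B cells lay at 1.65 ± 0.332 FPKM in untreated and 1.4 ± 0.553 in IL-4 cells (SD, n = 4). The platelet chemokine Pf4 was at 113 ± 49.1 and 175 ± 61.9, with a limma adjusted p of 0.169, of 0.0155 with the block and of 0.0486 without IL-4 replicate 1. The mitochondrially encoded mRNAs made up 7.78% ± 0.544 of summed FPKM without and 7.78% ± 0.455 with IL-4, and 0 of 13 were called. Median-ratio scaling changed the balance of calls in wild type to 1334 rises and 1210 falls, or 52.4% rises against 41.05%.

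In Sirt3 K223R macrophages Retnla, Chil3 and Arg1 rose with IL-4 as well. Retnla rose from 3.66 ± 4.09 to 5077 ± 1120 FPKM and Chil3 from 18.8 ± 6.25 to 6633 ± 388 (SD, n = 4). Fn1, the matrix protein fibronectin, rose from 0.793 ± 0.244 to 54.3 ± 18.5. Chil4, a close relative of Chil3, rose from at most 0.00309 in each untreated library to 16.7 ± 4.29. In all, limma called 4209 of 9891 genes, 1332 higher and 2877 lower, with 219 rises and 185 falls of at least 2-fold.

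Retnla rose by 10.48 (SE 0.45, adjusted p = 1.38e-10) on the log2(FPKM + 1) scale, Rnase2a by 8.52, Chil3 by 8.44 (SE 0.24), Arg1 by 7.03 (SE 0.26) and Mgl2 by 6.30. Fn1 (chromosome 1, 71585520 to 71653200) rose by 4.89 (SE 0.23, adjusted p = 3.15e-10), Ear2 by 4.76, Pdcd1lg2 by 4.49, Apol7c by 4.19 and Chil4 (chromosome 3, 106201490 to 106219507) by 4.12 (SE 0.12). Mrc1 rose by 2.22. Id3, an inhibitor of helix-loop-helix transcription factors, fell by 2.87 (SE 0.41). Also among the 10 largest falls were those of Ccl4 (-2.67), the acute-phase gene Saa3 (-2.61), Ccl3 (-2.46), the lipid-binding protein Fabp7 (-2.43), Ctla2b (-2.32), the ganglioside synthase St3gal5 (-2.26), Marcksl1 (-2.19) and Cd14 (-2.08). The complement receptor C5ar1 fell by 2.35, but it was at 23.3, 27.4, 256 and 214 FPKM in the 4 untreated libraries. Its call was lost without untreated replicate 3 (adjusted p = 0.0705), untreated replicate 4 (0.0659) or IL-4 replicate 2 (0.0503).

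Of the 32 IL-4 genes, 30 rose and 1, the transglutaminase Tgm2, fell (-0.28), with 30 and 1 adjusted over the list alone (camera adjusted p = 6.86e-33, and adjusted p = 0.000562 with an estimated correlation). The call for Tgm2 was lost without untreated Sirt3 K223R replicate 2 or IL-4 Sirt3 K223R replicate 3 (adjusted p up to 0.0581) and with median-ratio scaling (adjusted p = 0.167). For the tricarboxylic acid cycle 13 of 24 genes rose, such as Sdha (0.36) and Sdhd (0.27), and 1, Suclg2 (-0.74), fell, with 14 and 1 adjusted over the list alone (camera adjusted p = 4.84e-06, and adjusted p = 0.0142 with an estimated correlation). Of 7 osteoclast genes 6 rose, with Ocstamp at 2.91 and Itgb3 at 2.02, and 1, Nfatc1 (-0.20), fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 6.99e-05, and adjusted p = 0.0255 with an estimated correlation). The call for Nfatc1 was lost without IL-4 Sirt3 K223R replicate 2 (adjusted p = 0.052), with median-ratio scaling (adjusted p = 0.154) and with quantile normalization (0.147). Of 15 hypoxia genes 11 fell, and 11 adjusted over the list alone, with P4ha2 at -0.82 and the oxygen sensors Egln3 and Egln1 at -0.75 and -0.39 (camera adjusted p = 0.0027, and adjusted p = 0.0255 with an estimated correlation). In wild type 8 of them fell and 1, P4ha1 (0.20), rose, with the same counts adjusted over the list alone and an adjusted p of 0.0717 with camera, 0.16 with an estimated correlation and 1.47e-06 with fry.

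The other 8 lists called by camera in Sirt3 K223R cells lost their call with an estimated correlation. Fry kept the calls of all 12 camera lists. For oxidative phosphorylation 39 of 76 genes rose, such as Sdha and Atp5o (0.50), and 40 adjusted over the list alone (camera adjusted p = 1.61e-11, and adjusted p = 0.115 with an estimated correlation). For MHC class II presentation 8 of 8 genes rose, and 8 adjusted over the list alone, with Cd74 at 3.13, H2-DMa at 2.23 and the transactivator Ciita at 2.06 (camera adjusted p = 1.05e-07, and adjusted p = 0.13 with an estimated correlation). For cholesterol biosynthesis 15 of 22 rose, with Mvd at 0.68, and 1, Sc5d (-0.42), fell, with 15 and, Tm7sf2 being added, 2 adjusted over the list alone (camera adjusted p = 3.43e-06, and adjusted p = 0.115 with an estimated correlation). For fatty acid oxidation 9 of 23 rose, with Etfa at 0.49, and 2, Lipa (-0.41) and Cpt1a (-0.50), fell, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.00379, and adjusted p = 0.0811 with an estimated correlation). Among antioxidant genes 17 of 24 fell, with Gsr at -1.04 and Gclc, of glutathione synthesis, at -0.84, and 3, Slc7a11 (0.32), Nqo1 (0.55) and Gpx4 (0.16), rose, with 17 and 3 adjusted over the list alone (camera adjusted p = 0.00137, and adjusted p = 0.202 with an estimated correlation). The call for Gpx4 was lost without untreated Sirt3 K223R replicates 2, 3 and 4 or IL-4 Sirt3 K223R replicates 3 and 4 (adjusted p up to 0.0815) and in a fit on these groups alone (adjusted p = 0.0728). With quantile normalization its value turned to -0.01 (adjusted p = 0.909). Among inflammatory genes 7 of 12 fell, with Tnf at -1.74, and 1, Cd40 (0.47), rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.391 with an estimated correlation). The camera call of the inflammatory list was also lost without IL-4 replicate 2 (adjusted p = 0.0525). For lysosome and phagocytosis 11 of 28 rose and 6 fell, and 11 and 6 adjusted over the list alone, with Ctsz at 0.59 and the receptor Axl at -1.17 (camera adjusted p = 0.0253, and adjusted p = 0.191 with an estimated correlation). With quantile normalization the direction of the lysosome list turned and its call was lost (adjusted p = 0.594). Of 7 neutrophil genes 6 fell, and 6 adjusted over the list alone, with Ngp at -1.40 and Camp at -1.15 (camera adjusted p = 0.0253, and adjusted p = 0.391 with an estimated correlation).

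In Sirt3 K223R cells only other settings called the interferon and glycolysis lists. Of 28 type I interferon genes 16 fell, with the oligoadenylate synthetases Oas2 at -1.73 and Oas3 at -0.96, and 2, Usp18 (1.08) and Zbp1 (0.81), rose, with 17 and 2 adjusted over the list alone. The adjusted p was 0.101 with camera, 0.768 with an estimated correlation, 0.0354 with median-ratio scaling, 0.0262 with the replicate block and 0.0189 with fry. Of 20 glycolysis genes 9 fell, with Pfkl at -0.92 and Slc16a3 at -0.71, and 3 rose, with Pfkp at 0.77, or 11 and 3 adjusted over the list alone. The adjusted p was 0.205 with camera, 0.68 with an estimated correlation, 0.016 with quantile normalization, 0.0478 without IL-4 replicate 2 and 0.00189 with fry.

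Of the mitochondrially encoded mRNAs, 6 of 13 fell in Sirt3 K223R cells, and 6 adjusted over the list alone, such as mt-Nd3 (-0.64), mt-Nd1 (-0.57) and mt-Co2 (-0.34), while camera gave an adjusted p of 0.161. With quantile normalization that list was called (adjusted p = 0.00797), and with an estimated correlation it was not (adjusted p = 0.768). Their share of summed FPKM was 6.62% ± 0.31 without and 5.06% ± 1.24 with IL-4 (SD, n = 4). The shares differed by an exact permutation test (p = 0.0286), and replicate 2 with IL-4 was the lowest at 3.23%. Without that library the mean share with IL-4 was 5.67%, the median log2 change of these mRNAs went from -0.44 to -0.22, and 7 fell, 6 of the 6 above among them. Between the genotypes, 839 genes rose and 1292 fell in both responses, against 142 and 442 for independent lists, and 14 were called in opposite directions. Across the 9891 genes, which are not independent replicates, the responses correlated at 0.867 (Pearson) and 0.705 (Spearman). Of the genes called in Sirt3 K223R cells 31.65% rose as deposited, 51.1% (1957 against 1872) with median-ratio scaling and 44.9% (1644 against 2018) with quantile normalization.

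**Figure D2:**
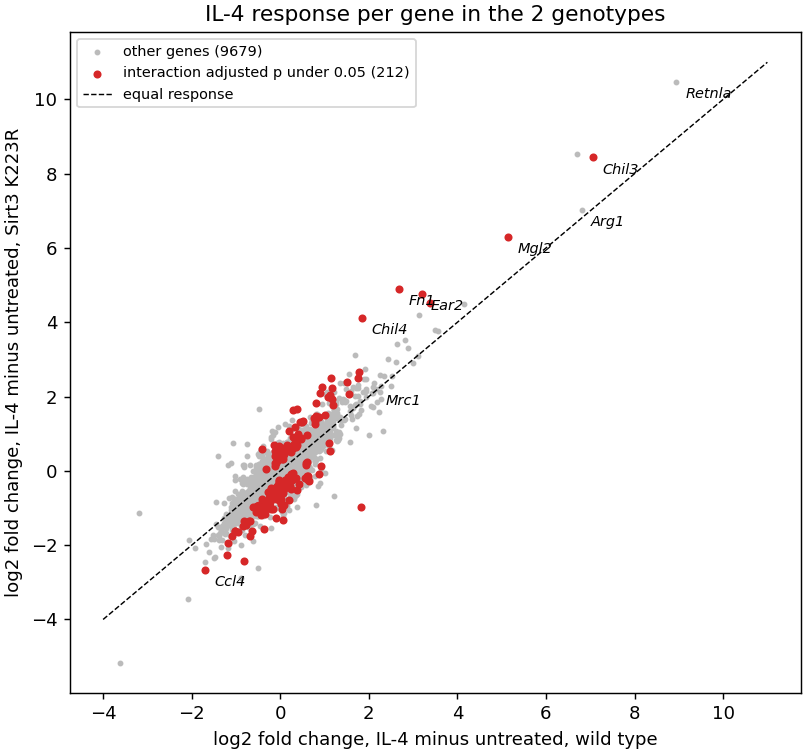
Each point is 1 of 9891 genes, with the log2 fold change of IL-4 against untreated cells in wild type (x axis) and in Sirt3 K223R (y axis), on the log2(FPKM + 1) scale; the dashed line marks equal responses and red points are the 212 genes called in the interaction. Chil4 and Fn1 lie above the line, Ccl4 below it, and Arg1 and Mrc1 close to it.

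Without IL-4 limma called 0 of 9891 genes between the genotypes. Unadjusted p was under 0.05 for 737 (7.45%), and the smallest adjusted p was 0.0982. Retnla was at 1.4 ± 0.578 FPKM in wild-type and 3.66 ± 4.09 in Sirt3 K223R cells, Chil3 at 13.8 ± 5.18 and 18.8 ± 6.25, Arg1 at 2.05 ± 1.32 and 1.84 ± 0.876, and Mrc1 at 47.2 ± 9.53 and 44.2 ± 4.01 (SD, n = 4). Their log2 differences were 0.57 (SE 0.45), 0.44 (SE 0.24), -0.06 (SE 0.26) and -0.07 (SE 0.12). With 191 calls simulations recovered 76.1% of changes of 0.5 and 97% of changes of 1. With few calls the cutoff is stricter and recovery lower.

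Camera at its preset correlation called 8 lists in untreated cells, none of which held with an estimated correlation or with fry, and no member of any of them passed over all genes. Type I interferon genes had a median log2 difference of 0.20 (camera adjusted p = 2.39e-10, and adjusted p = 0.561 with an estimated correlation). That of MHC class II genes was 0.37 (camera adjusted p = 0.0142, and adjusted p = 0.699 with an estimated correlation), and that of antioxidant genes 0.08 (camera adjusted p = 0.0142, and adjusted p = 0.561 with an estimated correlation). Inflammatory genes had a negative median, at -0.32 (camera adjusted p = 1.62e-05, and adjusted p = 0.427 with an estimated correlation). So had mitochondrially encoded mRNAs at -0.26 (camera adjusted p = 1.75e-05, and adjusted p = 0.561 with an estimated correlation) and oxidative phosphorylation at -0.08 (camera adjusted p = 1.15e-06, and adjusted p = 0.561 with an estimated correlation). The cell cycle lay at -0.08 (camera adjusted p = 0.00394, and adjusted p = 0.699 with an estimated correlation) and immediate early genes at -0.11 (camera adjusted p = 0.0273, and adjusted p = 0.561 with an estimated correlation). Adjusted over the list alone, 1 interferon gene, Oasl1 (0.59), was higher and 2 inflammatory genes, Ccl4 (-0.49) and Cxcl2 (-0.46), were lower, and the other 6 of these 8 lists had 0 members called. Among the lists that camera did not call or, with too few tested genes, did not test, the stromal genes Sparc (0.38) and Acta2 (0.44), the IL-4 gene Mmp13 (0.40) and the neutrophil gene Mmp8 (0.73) were higher when adjusted over the list alone. In the same way, Mdh1 (-0.23) of the tricarboxylic acid cycle, Egln3 (-0.32) of the hypoxia list, the histone gene Hist1h2ae (-0.69) and the B cell gene Cd79b (-0.36) were lower. With other settings of the test, up to 4 genes were called: Ctdsp2 with a fit on these groups alone (adjusted p = 0.00623), and Ttc14, Csnk1g1, Mid1 and Adam19 with array weights (adjusted p from 0.0313 to 0.0499). Leaving out 1 library called Ttc14 (wild-type replicate 1; adjusted p = 0.0205), Arfip2 and Oxnad1 (Sirt3 K223R replicate 2; 0.00723 and 0.0499) and Ino80d and Slx4ip (Sirt3 K223R replicate 3; 1.09e-07 and 0.0276). These genes were named after their values were seen. The mitochondrially encoded share was 7.78% ± 0.544 in wild-type and 6.62% ± 0.31 in Sirt3 K223R cells (SD, n = 4), which differed by an exact permutation test (p = 0.0286).

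**Figure D3:**
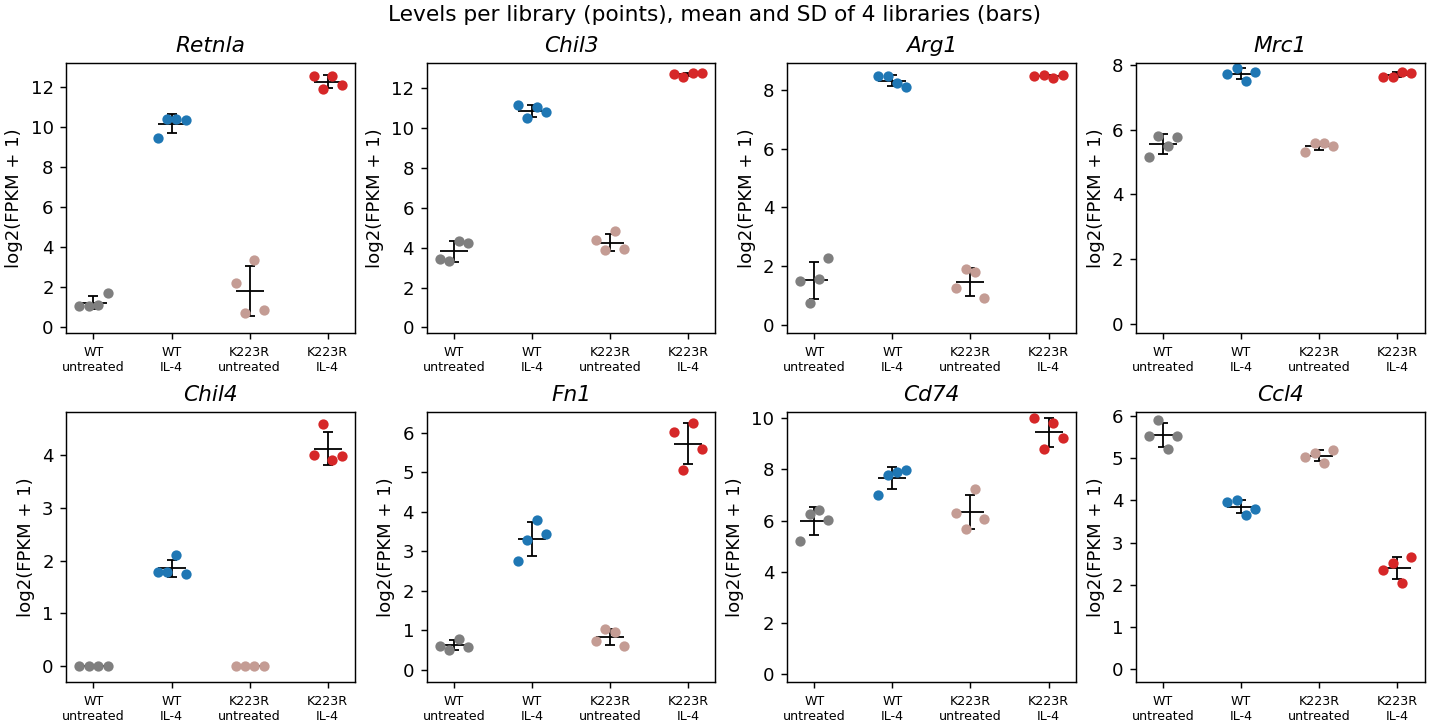
Levels of 8 genes on the log2(FPKM + 1) scale in each library (points), with the mean and SD of the 4 libraries of a group (bars), for untreated and IL-4 cells of both genotypes. Arg1 and Mrc1 reach like levels with IL-4 in both genotypes, while Retnla, Chil3, Chil4, Fn1 and Cd74 are higher and Ccl4 is lower in Sirt3 K223R cells with IL-4.

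With IL-4 the genotypes parted. Sirt3 K223R cells had more Retnla (5077 ± 1120 against 1200 ± 326 FPKM), Chil3 (6633 ± 388 against 1907 ± 384), Chil4 (16.7 ± 4.29 against 2.63 ± 0.438) and Fn1 (54.3 ± 18.5 against 9.27 ± 2.94; SD, n = 4). Arg1 (356 ± 12.2 against 320 ± 41.6) and Mrc1 (209 ± 12 against 213 ± 25.1) did not differ beyond the spread of the libraries. The MHC class II genes Cd74, H2-Ab1 and H2-Aa were higher and the chemokines Ccl4, Ccl2 and Ccl7 lower. Of 9891 genes, limma called 1487, 495 higher and 992 lower in Sirt3 K223R, of which 29 and 16 differed at least 2-fold.

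On the log2 scale, Fn1 was higher by 2.41 (SE 0.23, adjusted p = 2.15e-05), Chil4 by 2.27 (SE 0.12, adjusted p = 8.17e-08), and Ear2 by 2.23 (SE 0.24). Retnla was higher by 2.10 (SE 0.45, adjusted p = 0.00616), Rnase2a by 2.03 and Chil3 by 1.82 (SE 0.24, adjusted p = 0.000229). Rnase2a lost its call at a pseudocount of 0.1 (adjusted p = 0.059). Cd74 was higher by 1.79, H2-Ab1 by 1.67, H2-Aa by 1.56 and Cyp4f18, a fatty acid hydroxylase, by 1.57. Lower were Saa3 (-2.80, SE 0.43, adjusted p = 0.000712), Il11ra2 (-2.06), Fabp7 (-1.52), Ccl4 (-1.46), Marcksl1 (-1.29), the monocyte chemokines Ccl2 (-1.28) and Ccl7 (-1.15), Id1 (-1.23), St3gal5 (-1.18) and Il1b (-1.13). Il11ra2 has 2 identifiers in the files, and the values are those of the copy (ENSMUSG00000078735.3) with the higher mean over all libraries.

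Camera called 8 lists between genotypes with IL-4, and none held with an estimated correlation. Of 32 IL-4 genes, 10 were higher, with Mgl2 at 1.11, and 1, Tgm2 (-0.87), was lower. With p-values adjusted over the list alone the counts were 12 and, with the chemokines Ccl17 and Ccl22 added, 3 (camera adjusted p = 1.54e-06, and adjusted p = 0.117 with an estimated correlation). Of 8 MHC class II genes 7 were higher, and 7 adjusted over the list alone, with the transactivator Ciita at 1.44 (camera adjusted p = 1.87e-07, and adjusted p = 0.205 with an estimated correlation). Of 12 inflammatory genes 5, Ccl4 (-1.46), Ccl3 (-1.10), Tnf (-0.67), Il1b (-1.13) and Cxcl2 (-0.64), were lower, and 8 adjusted over the list alone (camera adjusted p = 0.000489, and adjusted p = 0.205 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 10 were lower, and 13 adjusted over the list alone, with mt-Nd3 at -0.94 (SE 0.17), mt-Nd1 at -0.82 (SE 0.15) and mt-Co2 at -0.55 (SE 0.09). Camera gave these mRNAs an adjusted p of 1.83e-06, and adjusted p = 0.34 with an estimated correlation. Their share was 7.78% ± 0.455 in wild-type and 5.06% ± 1.24 in Sirt3 K223R cells (SD, n = 4), with an exact permutation p of 0.0286. Without Sirt3 K223R replicate 2 the latter mean was 5.67%. Of 76 nuclear-encoded genes of oxidative phosphorylation 7 were lower and 0 higher. Adjusted over the list alone 4, Cycs (-0.39), Ndufs8 (-0.33), Atp5c1 (-0.40) and Ndufb6 (-0.28), were lower (camera adjusted p = 0.344). Over all genes, Atp5c1 lost its call in a fit on these groups alone (adjusted p = 0.0756) and Ndufb6 there (0.0831) and with median-ratio scaling (0.0652).

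**Figure D4:**
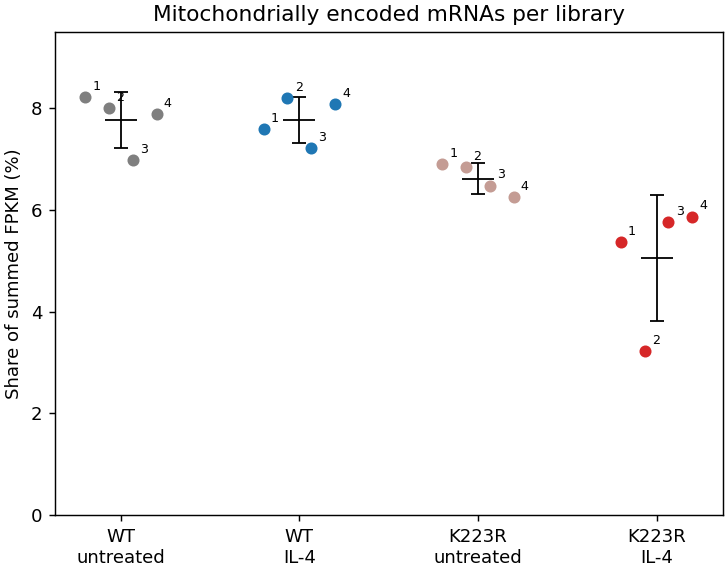
Share of summed FPKM in the 13 mitochondrially encoded mRNAs, in percent, per library (points with replicate numbers), with the mean and SD of the 4 libraries of each group (bars). The mean shares are 7.78% in both wild-type groups, 6.62% in untreated and 5.06% in IL-4 Sirt3 K223R cells, whose replicate 2 lies at 3.23%.

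Of 20 glycolysis genes 8 were lower in Sirt3 K223R cells with IL-4, such as the phosphofructokinase Pfkl (-0.43) and the lactate carrier Slc16a3 (-0.37), and 1, Pfkp (0.36), was higher, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.469 with an estimated correlation). Of 15 hypoxia genes 7 were lower, and 7 adjusted over the list alone, with Egln3 at -0.60 and P4ha1 at -0.42 (camera adjusted p = 0.0124, and adjusted p = 0.117 with an estimated correlation). The camera call was lost with quantile normalization (adjusted p = 0.0513). Of 22 cholesterol genes 3 were higher, among them Mvd (0.51) and Hmgcs1 (0.24), and 1, Tm7sf2 (-0.32), was lower, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.00225, and adjusted p = 0.34 with an estimated correlation and 0.0727 with fry). The call for Tm7sf2 was lost without IL-4 wild-type replicates 1 and 2 or IL-4 Sirt3 K223R replicates 1, 3 and 4 (adjusted p up to 0.112), with median-ratio scaling (adjusted p = 0.0836), with quantile normalization (0.102) and in a fit on these groups alone (0.121). Of 28 lysosome and phagocytosis genes 8 were higher and 1, Axl (-0.56), was lower, with 9 and, Msr1 being added, 2 adjusted over the list alone (camera adjusted p = 0.000586, and adjusted p = 0.117 with an estimated correlation). Scores of these 8 lists per library parted the genotypes with an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.0701. The share of called genes that were higher was 33.29% as deposited, 57.5% (825 against 610) with median-ratio scaling and 49.7% (697 against 705) with quantile normalization. A fit on these groups alone called 703 genes.

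Single markers of other cells also differed between genotypes with IL-4. Of 7 neutrophil genes 1, S100a8 (-0.65), was lower, also adjusted over the list alone, and camera gave an adjusted p of 0.713. The call for S100a8 was lost without IL-4 wild-type replicates 2, 3 and 4 or IL-4 Sirt3 K223R replicates 1, 2 and 4 (adjusted p up to 0.116), with median-ratio scaling (adjusted p = 0.0657), with quantile normalization (0.0573), with array weights (0.0626) and in a fit on these groups alone (0.108). Of the platelet genes Treml1 was lower (-0.70) and Pf4 was not called (0.74, adjusted p = 0.165). The B cell gene Cd79b (-0.47) passed when adjusted over the list alone, of which it was the single tested member, and not over all genes (adjusted p = 0.0671). It was called with array weights (adjusted p = 0.00977) and without IL-4 wild-type replicate 3 or IL-4 Sirt3 K223R replicate 2 (up to 0.0325). The block, with no pairing seen, called it too (adjusted p = 0.0203). In the same way the dendritic cell gene Batf3 (0.34) passed over its list alone, with an adjusted p of 0.121 over all genes. Of 7 osteoclast genes 1, the protease Mmp9 (0.99), was higher, and 2, with Acp5 (0.45), adjusted over the list alone (adjusted p = 0.0865 with camera, 0.34 with an estimated correlation and 0.0457 with fry). Over all genes Acp5 was called with median-ratio scaling (adjusted p = 0.0358), with the replicate block (0.0372) and without IL-4 Sirt3 K223R replicate 4 (adjusted p = 0.0458). Of 15 macrophage identity genes 2, Fcgr1 (-0.82) and Cd14 (-0.48), were lower. The stromal genes Acta2 (0.03) and Sparc (-0.14) and the erythroid gene Car2 (0.05) were not called.

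The interaction tested whether the IL-4 response itself differed between genotypes. Limma called it for 212 of 9891 genes, 77 with a more positive and 135 with a more negative response in Sirt3 K223R cells, and 185 of them had the larger response in Sirt3 K223R cells. Over all 2575 genes called in wild type, the response was larger in Sirt3 K223R cells for 1541 (59.8%), and the slope of the Sirt3 K223R on the wild-type response through 0 was 1.14. Chil4 and Fn1 rose more, and St3gal5 and Slc7a8 fell more, than in wild type. The transcription factor Klf2 went from 3.02 ± 0.526 to 3.88 ± 0.376 FPKM in wild-type and from 2.39 ± 0.25 to 9.6 ± 0.87 in Sirt3 K223R cells (SD, n = 4). Tgm2 went from 91.3 ± 12.2 to 142 ± 5.16 FPKM in wild type and from 93.6 ± 3.8 to 77.4 ± 8.25 in Sirt3 K223R cells.

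The interaction was 2.27 for Chil4 (SE 0.17, adjusted p = 1.08e-05), 2.20 for Fn1 (SE 0.33, adjusted p = 0.00436), 1.57 for Ear2, 1.38 for Chil3, and 1.37 for the interferon-induced GTPase Gbp2. It was 1.36 for Klf2 (SE 0.13, adjusted p = 0.000135), 1.30 for the eosinophil chemokine Ccl24, 1.28 for Tuba8, 1.19 for Aldh1a2, which makes retinoic acid, and 1.15 for Mgl2. It was -2.78 for Il11ra2 (SE 0.47, adjusted p = 0.0086), -1.61 for Fabp7, -1.38 for Tmeff1, -1.21 for the plasminogen activator Plau, -1.19 for Mapk1ip1, -1.07 for the amino acid carrier Slc7a8, -1.07 for St3gal5, -1.06 for Id2, -1.01 for the kinase Fgr and -0.97 for Havcr2. Retnla (1.53, SE 0.63, adjusted p = 0.246, and 0.0442 without untreated Sirt3 K223R replicate 3), Arg1 (0.22, SE 0.37) and Mrc1 (0.05, SE 0.18) were not called. Leaving out 1 library at a time, Gbp2 lost its call in 14 of 16 fits (adjusted p up to 0.0779), Chil3 in 11 (0.101) and Fabp7 in 11 (0.0792). Tmeff1 lost it in 10 (0.0777), Ccl24 in 9 (0.062), and Ear2 in 6 (0.0561) and Plau in 6 (0.0613). Mgl2 lost its call at a pseudocount of 0.1 (adjusted p = 0.148), and so did Chil3 (0.0661), which was also lost with no filter (0.0503) and with quantile normalization (0.12).

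Camera called 9 lists in the interaction. None held with an estimated correlation, and fry called only the hypoxia list (adjusted p = 0.00115). With the replicate number as a fixed block camera called 13 lists, these 9 and those of inflammatory (adjusted p = 0.0277), antioxidant (0.0205), neutrophil (0.0274) and osteoclast genes (0.0156). Without the block and with an estimated correlation the adjusted p of these added lists was 0.51, 0.51, 0.593 and 0.432. Of 32 IL-4 genes 4, Chil4, Mgl2, Ccl24 and Chil3, had a more positive and 1, Tgm2 (-0.92), a more negative response, with 6 and, Mmp13 being added, 2 adjusted over the list alone (camera adjusted p = 3.53e-05, and adjusted p = 0.209 with an estimated correlation). MHC class II genes had a median of 0.97, with 0 called over all genes and 3, Ciita (1.05), Cd74 (1.44) and H2-DMb1 (0.60), adjusted over the list alone (camera adjusted p = 3.53e-05, and adjusted p = 0.432 with an estimated correlation). With the fixed block, Cd74 (adjusted p = 0.0119), H2-Ab1 (0.0166) and Ciita (0.0355) were called over all genes. Mitochondrially encoded mRNAs had a median of -0.48, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.546 with an estimated correlation). Without IL-4 Sirt3 K223R replicate 2 their median was -0.25, with 1 called over all genes, mt-Nd1 (adjusted p = 0.028). In glycolysis 2 genes were lower, Pfkl (-0.44) and the glucose carrier Slc2a1 (-0.45), and adjusted over the list alone 8 were lower and 1, Pfkp, was higher (camera adjusted p = 0.0025, and adjusted p = 0.446 with an estimated correlation). In the hypoxia list 2 were lower, P4ha1 (-0.39) and Slc2a1, and adjusted over the list alone 5, with Vegfa, Pdk1 and Ankrd37 (camera adjusted p = 0.0245, and adjusted p = 0.209 with an estimated correlation).

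In the interferon list Usp18 had a more positive (0.87) and Irf7 (-0.80) and Oas3 (-0.73) a more negative response. With p-values adjusted over the list alone Oas2 and Xaf1 were added to the latter (1 and 4; camera adjusted p = 0.0118, and adjusted p = 0.589 with an estimated correlation). Cholesterol genes had a median of 0.05, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0359, and adjusted p = 0.51 with an estimated correlation). Its camera call was lost without IL-4 Sirt3 K223R replicate 2 (adjusted p = 0.115). In the cell cycle list 1 gene, Aurkb (0.64), was higher, and 1 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.576 with an estimated correlation). For lysosome and phagocytosis Axl was lower (-0.81) and 0 members were higher, the same adjusted over the list alone, while the median over the list was 0.10 and camera gave a positive direction (camera adjusted p = 0.00291, and adjusted p = 0.209 with an estimated correlation). With quantile normalization the camera calls of the lysosome (adjusted p = 0.176) and hypoxia lists (0.0566) were lost. Leaving out 1 library at a time, the calls were lost for Slc2a1 in 13 fits, Pfkl in 9, Oas3 in 8 and Irf7 in 7 (adjusted p up to 0.0977, 0.0653, 0.0653 and 0.0653). Aurkb lost its call without IL-4 wild-type replicate 3, untreated Sirt3 K223R replicate 2 or IL-4 Sirt3 K223R replicates 3 and 4 (adjusted p up to 0.0559). Pfkl and Slc2a1 also lost their calls with median-ratio scaling (adjusted p = 0.0767 and 0.0894) and quantile normalization (0.0785 and 0.0785).

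The number of interaction genes moved with single libraries. It was 112, 136 and 116 without Sirt3 K223R untreated replicates 2 and 3 and IL-4 replicate 3, and 130 and 131 without wild-type IL-4 replicates 3 and 4. It was 344 without IL-4 Sirt3 K223R replicate 2, and 207 of the 212 genes stayed called in the same direction there. With the replicate number as a fixed block it was 326 (173 of the 212 kept) and as a random effect 401 (212 kept), where the numbers were read as pairs in wild type alone. Other named genes called with the fixed block, and not without it, were S100a9 (0.0137), S100a8 (0.0342), Ddx3y (0.0337), Oas2 (0.0189), Vegfa (0.0187) and Xaf1 (0.0452), with the adjusted p in brackets. With array weights 465 genes were called. The share with a more positive response was 36.32% as deposited, 59.2% (132 against 91) with median-ratio scaling and 49.5% (104 against 106) with quantile normalization.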

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

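The tests of explanations and the counts over other splits of the libraries were chosen only after the results were seen.

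A share of 1 of 35 splits, the smallest possible, cannot exclude chance, and the other splits mix the real groups. For the IL-4 response in wild type, 1 of 35 splits of the 8 libraries, the real one, gave as many genes as 2575, and the highest of the others gave 6. Among the 8 splits that part all 4 same-numbered wild-type pairs, the highest of the others gave 0. For the IL-4 response in Sirt3 K223R it was 1 of 35 (4209 genes against 1), and for the genotype difference with IL-4 1 of 35 (1487 against 2). In untreated cells the real count was 0, which each split reaches by construction, so the splits say nothing there. The highest gave 2. For the interaction 2 of 100 drawn splits, the real one included, gave 212 genes or more. The other was the 1 draw that also parts the IL-4 libraries by genotype, with 1016 genes, and the highest of the rest gave 2. Those others also break up the genotype difference with IL-4, so the splits do not decide whether chance gives the interaction count. Chance was not excluded for the number of lists called by camera, and for the interaction lists the splits do not decide either. As many lists as in the real split were called, with the real number and the highest of the others in brackets, in 8 of 35 splits for the wild-type IL-4 response (9 and 12), 4 for that of Sirt3 K223R (12 and 14), 4 for genotype in untreated cells (8 and 13), 6 for genotype with IL-4 (8 and 12) and 5 of 100 for the interaction (9 and 10).

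The first pattern is the larger IL-4 response in Sirt3 K223R cells, where 212 genes had an interaction and 185 of them, chosen for a called difference, responded more in Sirt3 K223R, against 1541 (59.8%) of all 2575 genes called in wild type. Replicate 2 of Sirt3 K223R with IL-4, which stood apart, does not carry it alone, since 207 of the 212 genes stayed called in the same direction without it and their median absolute interaction was 0.50 against 0.49. Scaling is argued against for 168 of 212 calls, kept after median-ratio scaling (77 more positive, 91 more negative). Whether Sirt3 K223R still responds more is untested. A stronger IL-4 stimulus in these cultures cannot be told apart from an effect of the genotype, because no series of doses shows how each gene follows the stimulus, and 8 of the 31 IL-4 genes called in wild type responded less in Sirt3 K223R, 1 of them, Tgm2, with a called interaction. A difference between the genotypes in these IL-4-treated cultures, which may come from Sirt3 K223R, from the cultures or from the authors' processing, whose files differ in layout between the genotypes, stays open and untested.

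The second pattern is the lower level of mitochondrially encoded mRNAs in Sirt3 K223R cells with IL-4. All 10 of the 10 members called lower stayed called lower without replicate 2, although their median went from -0.73 to -0.50, and 9 stayed called after median-ratio scaling (median -0.67). A different enrichment of mRNA between the genotypes could lower these mRNAs, since the labels leave open which libraries had poly(A) selection. Replication-dependent histone mRNAs, which lack a poly(A) tail, had a median of 0.13 with IL-4 (Sirt3 K223R minus wild type) over 9 genes, with Hist1h1c (0.94) and Hist1h2bc (0.43, not called without IL-4 wild-type replicates 1, 2 and 4 or IL-4 Sirt3 K223R replicates 1, 3 and 4 (adjusted p up to 0.111) or in a fit on these groups alone (0.114)) higher and Hist1h2ae (-1.09) lower, so this explanation cannot be told apart from an effect of the genotype.

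The third pattern is the higher Chil4 in Sirt3 K223R cells with IL-4. If reads of the similar Chil3 were its source, Chil4 would be a fixed share of Chil3. Chil4 was 2.03 to 3.82 per 1000 FPKM of Chil3 in Sirt3 K223R against 1.06 to 1.69 in wild type. The lack of overlap argues against such reads as the whole source. The mean, 1.82 times as high, was not taken without replicate 2, highest for Chil4 and lowest for Chil3. Regulation of Chil4 apart from Chil3 is a candidate, found and tested on the same data.

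The test of the difference between the IL-4 responses of the genotypes marked the 212 genes above, and among the genes named here the following log2 differences. More positive responses in Sirt3 K223R were those of Chil4 (2.27), Fn1 (2.20), Ear2 (1.57), Chil3 (1.38), Gbp2 (1.37), Klf2 (1.36), Ccl24 (1.30), Tuba8 (1.28), Aldh1a2 (1.19), Mgl2 (1.15), Slx4ip (0.99), Usp18 (0.87), Hist1h1c (0.85), Aurkb (0.64) and Got1 (0.53). More negative responses were those of Il11ra2 (-2.78), Fabp7 (-1.61), Tmeff1 (-1.38), Plau (-1.21), Mapk1ip1 (-1.19), Slc7a8 (-1.07), St3gal5 (-1.07), Id2 (-1.06), Fgr (-1.01), Ccl4 (-0.97), Havcr2 (-0.97), Ccl2 (-0.95), Tgm2 (-0.92), Axl (-0.81), Irf7 (-0.80), Oas3 (-0.73), Fcgr1 (-0.70), Gclc (-0.59), Sparc (-0.52), Taldo1 (-0.48), Slc2a1 (-0.45), Lpl (-0.44), Pfkl (-0.44), P4ha1 (-0.39) and Atf4 (-0.29). Some of these calls, chosen for mention after the values were seen, did not hold in each setting. Leaving out 1 library at a time ended the call of Lpl in 13 of 16 fits (adjusted p up to 0.103), of Fcgr1 in 12 (0.0779), of Atf4 in 10 (0.0653) and of Ccl4 in 1 (0.05001). Median-ratio scaling ended those of Lpl (adjusted p = 0.136), Fcgr1 (0.055) and Atf4 (0.0897), and fitting with no filter that of Lpl (0.052).

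Camera marked 9 lists in the interaction. The adjusted p was 3.53e-05 for IL-4 alternative activation, 0.0118 for type I interferon response, 0.0101 for mitochondrially encoded mRNAs, 0.0025 for glycolysis, 0.0359 for cholesterol biosynthesis, 0.013 for cell cycle, 3.53e-05 for MHC class II presentation, 0.00291 for lysosome and phagocytosis and 0.0245 for hypoxia. None of them was called with an estimated correlation (adjusted p from 0.209 to 0.589), and fry called only hypoxia (adjusted p = 0.00115).

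In 72 of 889 groups of 4 libraries (8.1%), 1 library lay far from the other 3, measured as its gap to the nearest divided by the whole range; chance alone marks about 1 in 20. The values were genes in 62 of 765 groups, library measures in 2 of 16 and list scores in 8 of 108. Replicate 2 of Sirt3 K223R with IL-4 and replicate 3 of untreated wild type were the libraries most often apart (9 times each, of the values named here), followed by replicate 1 of wild type with IL-4 (8). IL-4 Sirt3 K223R replicate 1 was the highest for Oas3 (0.903). IL-4 Sirt3 K223R replicate 2 was the highest for Chil4 (0.871), Ctsz (0.871), Cd79b (0.868) and Bst2 (0.868) and the lowest for Chil3 (0.879), Ctla2b (0.882), mt-Co1 (0.858), Gclc (0.918) and the list score of mitochondrially encoded mRNAs (0.841). IL-4 Sirt3 K223R replicate 3 was the highest for Cxcl2 (0.907) and Abcg1 (0.894). IL-4 Sirt3 K223R replicate 4 was the highest for Hmgcs1 (0.841). Untreated Sirt3 K223R replicate 1 was the highest for Gpx4 (0.938) and the lowest for Aurkb (0.858), Ric8a (0.878) and the list score of cell cycle (0.846). Untreated Sirt3 K223R replicate 2 was the highest for Saa3 (0.839), Il1b (0.885), Aldh1a2 (1.0) and Arfip2 (0.85). Untreated Sirt3 K223R replicate 3 was the highest for Ear2 (0.862), Tuba8 (1.0), Ino80d (0.995), Lipa (0.835), Slx4ip (0.854) and median FPKM (0.931). Untreated Sirt3 K223R replicate 4 was the highest for H2-DMb1 (0.89), Srebf1 (0.864) and Rpl29 (0.864). IL-4 wild-type replicate 1 was the highest for Klf2 (0.852), Ccl24 (0.913) and the list score of C57BL/6 substrain (0.869) and the lowest for Retnla (0.893), mt-Co2 (0.852), Gbp2 (0.944), Mapk1ip1 (0.9) and the list score of replication-dependent histones (0.953). IL-4 wild-type replicate 2 was the highest for Il4i1 (0.98) and Il11ra2 (0.902) and the lowest for Fgr (0.842). IL-4 wild-type replicate 3 was the highest for Chil4 (0.903), Id1 (0.877), Axl (0.83) and Ccl17 (0.878) and the lowest for Hadha (0.833). IL-4 wild-type replicate 4 was the highest for the list score of sex-linked (0.952). Untreated wild-type replicate 1 was the highest for Ctsk (0.838) and the list score of osteoclast (0.89) and the lowest for Arhgap19 (0.867) and Lgmn (0.839). Untreated wild-type replicate 2 was the highest for Csnk1g1 (0.841), Ndufb6 (0.862) and sum of FPKM (0.895) and the lowest for Gclc (0.868), Senp2 (0.852) and the list score of tricarboxylic acid cycle (0.887). Untreated wild-type replicate 3 was the highest for Il11ra2 (0.896), Aldh1a2 (1.0), Camp (0.896), Ear10 (0.832) and the list score of sirtuins and SUMO pathway (0.89) and the lowest for Idh3a (0.894), Ocstamp (0.943), mt-Nd1 (0.92) and Ddx3y (0.909). Untreated wild-type replicate 4 was the highest for Retnla (0.91), Apol7c (1.0), C5ar1 (0.966) and Gbp2 (0.982) and the lowest for Mid1 (0.903) and Tm7sf2 (0.915).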

How the results depend on the processing

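The camera tests, the correlation and the medians and counts of mitochondrially encoded mRNAs without replicate 2 of Sirt3 K223R with IL-4 were chosen only after the data were seen, and all other settings were fixed before. The cause was not tested for any change below, apart from the 2-fold minimum, which lowers counts by its construction.

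Some numbers of genes called by limma moved by over 1.5 times. With a minimum of 2-fold, 248, 404, 45 and 22 genes were called for IL-4 in wild type, IL-4 in Sirt3 K223R, genotype with IL-4 and the interaction. A fit on the compared groups alone called 703 genes for genotype with IL-4 and 1 for genotype in untreated cells, and array weights called 4 there and 465 for the interaction (211 of the 212 kept). Leaving out 1 library gave 2189 to 2519 genes for IL-4 in wild type, 3651 to 4128 for IL-4 in Sirt3 K223R, 0 to 2 for genotype in untreated cells, 1201 to 1573 for genotype with IL-4 and 112 to 344 for the interaction. These stayed within 1.5 times of the count on all libraries for both IL-4 responses and for genotype with IL-4, and went beyond it for genotype in untreated cells and the interaction. The lowest interaction count came without untreated Sirt3 K223R replicate 2 and the highest without replicate 2 with IL-4. Median-ratio scaling, which moved none of these counts by over 1.5 times, kept 2267 of 2575, 3204 of 4209, 1104 of 1487 and 168 of 212 genes in the same direction. Median-ratio scaling moved the exact p for Sirt3 with IL-4 in Sirt3 K223R from 0.0286 to 0.171.

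With the replicate number as a fixed block 2707, 4305, 0, 1476 and 326 genes were called for IL-4 in wild type, IL-4 in Sirt3 K223R, genotype in untreated cells, genotype with IL-4 and the interaction, and as a random effect 2930, 4606, 0, 1487 and 401. Of the 212 interaction genes 173 were kept with the fixed and 212 with the random block. In Sirt3 K223R the same-numbered pairs correlated at 0.0524, 0.083, 0.127 and -0.0452, and not each library was closest to its own number, so pairing is undecided there. The block moved the interaction count alone by over 1.5 times. For the wild-type response the fixed block changed the call of the neutrophil list and, among named genes, of Pf4 (adjusted p = 0.0155), Ctsk (0.0228), Mmp9 (0.00299), Nqo1 (0.0156), S100a8 (0.00443) and Ccr2 (0.0201), and of no other. As a random effect it changed the calls of Ctsk (adjusted p = 0.0433), Mmp9 (0.0302), Nqo1 (0.0467), S100a8 (0.041) and Tkt (0.0379) and of no other named gene.

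Camera called 46 lists over the 5 comparisons, 6 with an estimated correlation, 46 with fry, 49 with median-ratio scaling, 46 with quantile normalization and 53 with the fixed block. Without replicate 2 of Sirt3 K223R with IL-4 it called 12 (11 kept) for IL-4 in Sirt3 K223R, 8 (8 kept) for genotype with IL-4 and 9 (8 kept) for the interaction. The direction of the lysosome and phagocytosis list turned with IL-4 in Sirt3 K223R under quantile normalization (adjusted p = 0.594). Fry called the neighbours of Sirt3 lower (adjusted p = 0.000273 with IL-4 in Sirt3 K223R and 0.0269 for genotype with IL-4). Camera ranks lists against other genes, so its opposite, uncalled sign there is no reversal. Other lists gained a call with fry, for IL-4 in wild type those of immediate early genes (adjusted p = 0.0115), substrain genes (0.00432) and neighbours of Sirt3 (0.00537), and for IL-4 in Sirt3 K223R those of immediate early genes (0.00191), substrain genes (0.000191, and 0.0365 with the block) and sirtuins and SUMO (0.000374). In the interaction the inflammatory (0.0319) and tricarboxylic acid cycle lists (0.0488) gained a call with median-ratio scaling, the antioxidant list with quantile normalization (0.0147) and histones without replicate 2 (0.0495). No list gained a call with an estimated correlation. For Gpx4 with IL-4 in Sirt3 K223R quantile normalization turned the value to -0.0079. Over the genes named here and the settings run for them, with the least favourable of the fits that leave out 1 library counted once per gene, 4713 values kept their direction and call, 45 changed sign between values that were not called, 416 lost the call, 75 gained it and 1 turned. Of the lost calls 242 were under the 2-fold minimum. For lists the numbers were 608, 52, 62, 31 and 3 (2 under fry, as above). The correlation of the IL-4 responses between genotypes lay between 0.852 and 0.867 over the main setting, a pseudocount of 0.1, no filter, both scalings and the fit without replicate 2. The sequencing depth is unknown, so its limits for low genes could not be given. A test planned for read counts was not run, as the values are not whole counts.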

Other observations

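The gene groups in this part were fixed before the data were examined, and the comparison of values inside a group of libraries was chosen only after they were seen.

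Genes of cholesterol efflux under the liver X receptors differed between the genotypes with IL-4 in both directions. Of 12 tested members 5 were higher in Sirt3 K223R, the lipid exporters Abca1 (0.72) and Abcg1 (0.53), the transfer protein Pltp (0.73), the desaturase Scd2 (0.49) and Srebf1 (0.24), and 3 were lower, the lipoprotein lipase Lpl (-0.38), Apoe (-0.57) and Apoc1 (-0.83). Adjusted over the list alone the counts were 5 and, with Nr1h3 added, 4, and camera gave an adjusted p of 0.163. The calls were lost for Apoe without IL-4 wild-type replicates 3 and 4 (adjusted p up to 0.0532) and with quantile normalization (adjusted p = 0.0871), for Srebf1 without IL-4 wild-type replicates 2 and 4 or IL-4 Sirt3 K223R replicates 1 and 2 (adjusted p up to 0.0897), and for Apoc1 without IL-4 wild-type replicates 2, 3 and 4 or IL-4 Sirt3 K223R replicates 2 and 4 (adjusted p up to 0.133) and with median-ratio scaling (adjusted p = 0.0611) or no filter (0.051). Among the lysosomal genes higher in Sirt3 K223R with IL-4 were the protease Lgmn (0.33), the saposin precursor Psap (0.47) and the cathepsin Ctsz (0.19). Psap lost its call with quantile normalization (adjusted p = 0.076) and Ctsz in a fit on these groups alone (adjusted p = 0.0709).

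In the list for ATF4 and amino acid stress, 3 of 16 members were lower in Sirt3 K223R with IL-4, the transcription factor Atf4 (-0.32), the asparagine synthetase Asns (-0.52) and Shmt2 (-0.19), and 2 were higher, Sesn2 (0.37) and Ddit3 (0.26), with the same counts adjusted over the list alone (camera adjusted p = 0.968). The call for Shmt2 was lost without IL-4 wild-type replicates 1, 2, 3 and 4 or IL-4 Sirt3 K223R replicates 1, 3 and 4 (adjusted p up to 0.127), with no filter (adjusted p = 0.0528), with median-ratio scaling (0.189) and with quantile normalization (0.19), and that for Ddit3 without IL-4 wild-type replicates 1, 2 and 3 or IL-4 Sirt3 K223R replicates 1, 3 and 4 (adjusted p up to 0.104).

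Among lists that camera did not call for genotype with IL-4, 3 of 17 genes of glutamine and alpha-ketoglutarate metabolism were higher in Sirt3 K223R, Got1 (0.39), Bcat2 (0.28) and Glul (0.26), and 1, Asns (-0.52), was lower (camera adjusted p = 0.344). Of 16 histone demethylases that depend on alpha-ketoglutarate 3 were higher, Kdm6b (0.37), Kdm5b (0.20) and Kdm4b (0.24), and 1, Kdm7a (-0.38), was lower (0.247). The counts were the same adjusted over each list alone. Of 23 genes of sirtuins and the SUMO pathway 2, Sumo2 (-0.30) and Senp2 (-0.19), were lower, and 0 adjusted over the list alone (adjusted p = 0.479 with camera, 0.713 with an estimated correlation and 0.0289 with fry). These members were named after their values were seen. Leaving out 1 library at a time, the calls were lost for Bcat2 and Glul in 3 fits each (adjusted p up to 0.0571 and 0.0584), Kdm6b and Kdm7a in 4 each (0.0674 and 0.0863), Kdm5b and Kdm4b in 6 each (0.0939 and 0.132), Sumo2 in 3 (0.0742) and Senp2 in 7 (0.119). A fit on these groups alone ended the calls of all of these but Glul (adjusted p from 0.0975 to 0.128). The call was also lost for Glul with quantile normalization (adjusted p = 0.0651), for Kdm4b with no filter (0.0527) or array weights (0.0578), and for Senp2 with either scaling (0.15 and 0.109) or array weights (0.053).

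Transcripts of the Y chromosome were present in every group, with Ddx3y at 16.1 ± 3.39 FPKM in untreated and 15.5 ± 2.06 in IL-4 wild-type cells and at 16.7 ± 0.891 and 11.2 ± 1.14 in Sirt3 K223R cells (SD, n = 4). With IL-4, Ddx3y was lower in Sirt3 K223R (-0.43), and adjusted over the list of 4 sex-linked genes alone Eif2s3y (-0.29) was too. The call for Ddx3y was lost without IL-4 wild-type replicates 1, 2 and 4 or IL-4 Sirt3 K223R replicates 2, 3 and 4 (adjusted p up to 0.105), with median-ratio scaling (adjusted p = 0.0651) and with quantile normalization (0.0646). Nnt, a mitochondrial transhydrogenase that part of the C57BL/6 substrains lack in full length, was at 5.54 ± 1.35 and 4.53 ± 1.18 in wild-type and 5.11 ± 0.895 and 4.42 ± 1.09 in Sirt3 K223R cells, with log2 differences between genotypes of -0.09 (SE 0.19, limma adjusted p = 0.987) without and -0.03 (SE 0.19, limma adjusted p = 0.941) with IL-4. Of 5 tested genes that differ between substrains, 0 were called with IL-4 over all genes and 2, Cyfip2 (-0.37) and Ide (-0.22), were lower when adjusted over the list alone. The list had an adjusted p of 0.328 with camera, 0.513 with an estimated correlation and 0.0457 with fry, and its score an exact permutation p of 0.0286 (adjusted p = 0.0701). Over all genes Cyfip2 was called with the replicate number as a random effect (adjusted p = 0.0435), with array weights (0.0191) and without IL-4 wild-type replicate 3 or IL-4 Sirt3 K223R replicate 2 (adjusted p up to 0.0305), and Ide without IL-4 wild-type replicate 3 (adjusted p = 0.0409). Without IL-4, 0 members were called over the list alone. Of 22 tested neighbours of Sirt3 on chromosome 7, 1 was higher and 4 were lower in Sirt3 K223R with IL-4, Ric8a (0.20), Taldo1 (-0.41), Irf7 (-0.54), Ifitm1 (-0.48) and Ifitm3 (-0.50), named after their values were seen, and 0 were called in untreated cells. The calls were lost for Ric8a without IL-4 wild-type replicates 2 and 3 or IL-4 Sirt3 K223R replicates 1, 2, 3 and 4 (adjusted p up to 0.121) and with no filter (adjusted p = 0.051), for Ifitm1 without IL-4 wild-type replicates 2 and 3 or IL-4 Sirt3 K223R replicate 2 (adjusted p up to 0.0784), and for Ifitm3 without IL-4 wild-type replicates 2 and 4 or IL-4 Sirt3 K223R replicates 2 and 4 (adjusted p up to 0.0985) and with median-ratio scaling (adjusted p = 0.0615).

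Some genes spread widely between libraries of a single group. Of the genes with a mean of at least 10 FPKM, 14 had a highest value at least 8 times the lowest within at least 1 group, in 20 gene and group combinations. The range was 4.04 to 84.9 FPKM for Apoc2 in untreated wild type, 15.2 to 191 for the ribosomal protein gene Rpl29 in wild type with IL-4, 23.3 to 256 for C5ar1 in untreated Sirt3 K223R and 0.106 to 22.6 for Ear10 in Sirt3 K223R with IL-4, named after their values were seen.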
